A study of Bos taurus with 6 samples.

How the data were processed

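Messenger RNA libraries were made from total RNA of bovine metaphase II oocytes extracted with TRIzol, using a BGI Optimal Dual-mode library kit, per the labels' protocols. The authors deposited, for each of the 6 libraries, an FPKM value with 2 decimals for the same 17325 genes. The submitters' processing notes name HISAT2 2.2.1, Bowtie2 2.3.4.3, RSEM 1.3.1 and DESeq2 1.4.5 and the genome build ARS-UCD1.2, without giving the role or order of each tool. How reads shared between similar genes were divided, and whether strand was used, is not given in the sources used here, so values of near-identical copies are uncertain. FPKM divides by transcript length and library total, so a gene that takes a large share of one library lowers all others there.

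The 6 samples were grouped by their titles, which begin with NC or siMTFP1, into 3 negative control and 3 MTFP1 knockdown libraries. Each gene was identified by its NCBI gene ID and symbol. In the files 24 symbols had been turned into dates by spreadsheet software and were restored from the gene ID, and 17087 of the 17325 IDs matched the RefSeq table of assembly ARS-UCD2.0, which was used for names only. Because the builds differ, no coordinates are printed. The 13 mitochondrially encoded protein genes matched 0 symbols, so that list was not analysed here.

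Sequencing depth per library is unknown, because FPKM keeps no read totals, and no counting interval or detection floor is given. As a hint at relative depth, the commonest log2 ratio of low values lay within 0.1 of 0 in 13 of 15 pairs of libraries. Genes at 0 numbered 1792 to 2205 per library, and 7 genes were at 0 in all.

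Values were transformed as log2(FPKM + 1), genes with a mean FPKM of at least 1 over the 6 libraries were kept (9730 genes), and the groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided moderated test, group as the only term). Benjamini-Hochberg adjustment was made over the tested genes, at a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low values. A count model could not be used because the values are not counts. MTFP1 was also compared by an exact two-sided permutation test of its log2 values, whose smallest p with 3 against 3 is 0.1.

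Of 35 gene lists fixed before the data were examined, 33 had at least 5 tested members and were tested with camera (preset correlation 0.01, adjusted over the lists), and beside it with camera at an estimated correlation and with fry, which asks whether the genes of a list move without comparing them with other genes. Members of each list were also adjusted over the list alone. The rule for named genes was also fixed before the data were examined: MTFP1, up to 12 genes per direction past the threshold without overlap between groups, otherwise the 5 with the smallest p per direction among genes with a symbol that is not a LOC number, and up to 4 members per list with the smallest p. From these the text names those it needs, and other genes are marked as chosen after their values were seen.

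The test was run first on simulated data for 9730 genes with 200 changed genes, in 20 simulations. The share of false calls was 4.78%, and a list shifted by 0.5 was called in 20 of 20 simulations. The simulated genes varied independently, so these runs do not test camera or limma where genes are correlated. In the real libraries the estimated correlation was 0.149 in the interferon list and 0.595 in the cytosolic ribosomal list. Alternatives were other pseudocounts (0.1 and 5), filters (none, 0.1 and 5), scalings (to equal sums, median ratio, quantile), the replicate number as a block, array weights, robust eBayes, a fold change minimum and leaving out each library in turn. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.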

Results

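RNA was sequenced from bovine oocytes matured in vitro to metaphase II, the stage at which the egg awaits fertilization. 3 libraries are labelled negative control and 3 are labelled MTFP1 knockdown, and the design holds this one comparison, of the transcriptome between the groups. MTFP1 encodes a protein of the inner mitochondrial membrane linked to mitochondrial fission. Each library gave FPKM (fragments per kilobase of transcript, scaled to the library's mapped fragments) for the same 17325 genes, of which 15120 to 15533 per library lay above 0. The FPKM values of a library summed to between 784366 and 892790.4, and its 10 most abundant genes took 19.9% to 22.8% of that sum. Sequencing depth is unknown, because FPKM carries no read total.

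The oocyte genes BTG4, H1FOO and GDF9 were abundant in both groups. BTG4, an adaptor for the decay of maternal mRNA, averaged 10610 ± 1322 FPKM (SD, n = 3) in the libraries labelled control and 9630.5 ± 463 in those labelled knockdown. The oocyte linker histone H1FOO averaged 6431 ± 338 and 7203 ± 597 FPKM, and the oocyte growth factor GDF9 averaged 288 ± 30.5 and 316 ± 33.6 FPKM. BTG4, H1FOO and GDF9 were chosen as examples after their values were seen. Pairwise correlations of the log2 values across genes lay between 0.971 and 0.986, with a mean of 0.982 within groups and 0.980 between groups, genes not being independent replicates.

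MTFP1 itself (NCBI gene ID 525071) lay near 0 in every library and was not lower in the libraries labelled knockdown. Its FPKM was 0.53, 0.55 and 0.05 in the libraries labelled control 1, 2 and 3. In the libraries labelled knockdown 1, 2 and 3 it was 0.43, 0.58 and 1.15. The means were 0.377 ± 0.283 and 0.720 ± 0.380 FPKM (SD, n = 3), a difference of 0.32 on the log2(FPKM + 1) scale (exact two-sided permutation test, p = 0.4, where the smallest possible p is 0.1). The difference was 0.14 without control 3 and 0.15 without knockdown 3 (exact permutation p = 0.8 for each). MTFP1 lay below the expression filter, and limma without that filter gave a Benjamini-Hochberg adjusted p of 0.886. The targeted transcript did not follow the labels, so the groups are called by their labels throughout, and every direction is that of the labels.

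**Figure D1:**
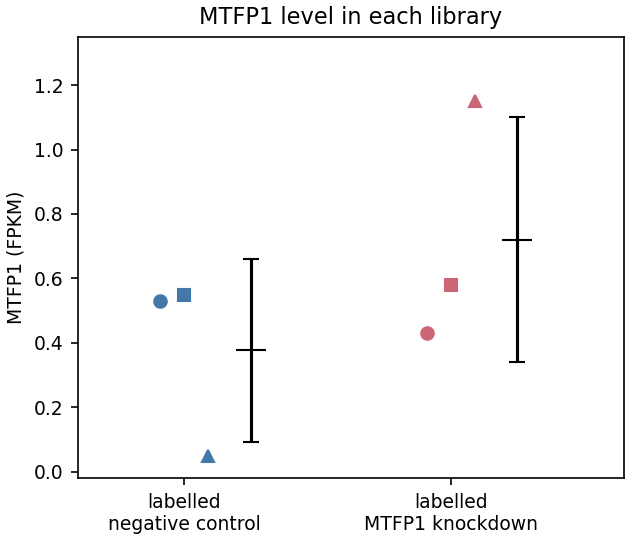
MTFP1 level in FPKM (vertical axis) for the 3 libraries labelled negative control and the 3 labelled MTFP1 knockdown, with circles, squares and triangles for replicates 1, 2 and 3 and the bar showing the mean and 1 SD. The libraries labelled knockdown lie between 0.43 and 1.15, and those labelled control between 0.05 and 0.55.

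The genes with the 2 smallest p-values belong to the interferon response, and both were at higher levels in the libraries labelled knockdown. ISG15, a ubiquitin-like modifier made in response to interferon, averaged 4.96 ± 3.18 FPKM (SD, n = 3) in the libraries labelled control and 86.3 ± 45.9 in those labelled knockdown. The log2 difference was 3.89 (SE 0.44). IFI6, an interferon-inducible protein that restrains apoptosis, averaged 2.37 ± 0.636 and 47.2 ± 34.3 FPKM, a log2 difference of 3.63 (SE 0.42). For both genes each of the 3 libraries labelled knockdown lay above each of the 3 labelled control. Neither passed the threshold over all 9730 tested genes (limma with Benjamini-Hochberg, adjusted p = 0.0828 for each). Both passed with FPKM rescaled to equal sums (limma adjusted p = 0.0182 for each) or with only genes of a mean FPKM of at least 5 tested (0.0389 for each), ISG15 also with the cumulus marker mean as a covariate (0.00152), a fit added after the result was seen, and IFI6 also without knockdown 2 (0.0127) or knockdown 3 (0.0421). Over all settings, the covariate included, the limma adjusted p ranged from 0.00152 to 0.698 for ISG15 and from 0.0127 to 0.698 for IFI6.

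The fixed list for the interferon and double-stranded RNA response had 18 tested members of 31 matched. Of the tested ones 14 had a higher and 4 a lower mean in the libraries labelled knockdown, with a median log2 difference of 0.34. The untested members lay below the expression filter and went both ways, with group means of at most 1.02 FPKM. This list was tested with camera and fry. It was the list with the smallest p (camera, Benjamini-Hochberg adjusted p = 8.35e-06 with a preset correlation of 0.01). The call was lost with an estimated correlation (camera p = 0.0410 before and 0.965 after adjustment). The fry test gave adjusted p = 0.677 (0.0205 before adjustment) for movement in one direction. For change in either direction fry gave adjusted p = 0.119 (0.00362 before adjustment). By limma, 6 members passed adjusted over the list alone and 0 over all genes: ISG15, IFI6, IFI27, MX1, OAS1Y and USP18. The interferon-inducible gene IFI27 averaged 5.14 ± 3.59 and 31.3 ± 11.0 FPKM, and the antiviral GTPase gene MX1 averaged 0.643 ± 0.837 and 4.63 ± 3.12. OAS1Y, an oligoadenylate synthetase, had a log2 difference of 1.95 (SE 0.57), a value that is uncertain because near-identical OAS1 copies can share reads. USP18, the protease that removes ISG15 from proteins, averaged 0.337 ± 0.0757 and 1.96 ± 1.64 FPKM. MX1 and USP18 passed the mean FPKM filter of 1 only through their levels in the libraries labelled knockdown. OAS1Y and USP18, which complete the 6, and IFIT3 were chosen after their values were seen. The antiviral gene IFIT3 of the same list averaged 3.73 ± 1.16 and 3.13 ± 0.123 FPKM, with a log2 difference of -0.16. Without the 6 leading members the camera adjusted p of the list was 0.499, a weakening bound to follow because these members were picked by their p-values. The mean log2 level of the cumulus and granulosa markers was 3.67, 2.75 and 3.44 in the libraries labelled control and 3.21, 3.80 and 3.30 in those labelled knockdown. Knockdown 2 had the highest value of this mean and of ISG15 (138.75 FPKM), IFI6 (86.4), MX1 (8.23), OAS1Y (16.09) and USP18 (3.85).

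**Figure D2:**
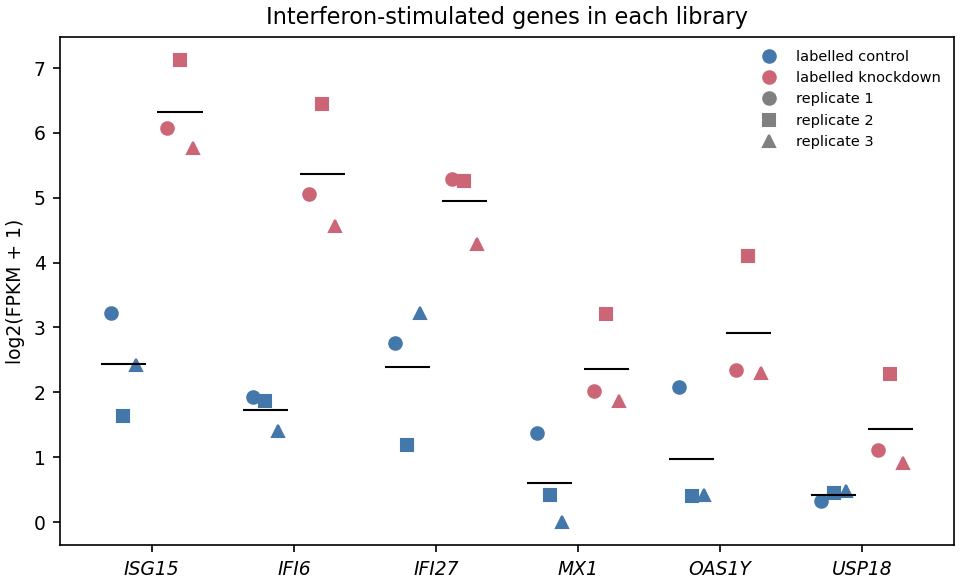
Level of 6 interferon-stimulated genes as log2(FPKM + 1) (vertical axis) in each library, blue for the 3 labelled control and red for the 3 labelled knockdown, with marker shapes for replicates 1, 2 and 3 and horizontal lines at the group means. For each of the 6 genes the libraries labelled knockdown lie above those labelled control, and the difference between group means runs from 1.02 (USP18) to 3.89 (ISG15).

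Among genes outside that list with a symbol other than a LOC number, CRABP2, TSPAN6 and PPP1R18 had the smallest p-values in the higher direction, and ZP2, GTPBP10, AVPR1B, ZWILCH and RSBN1L in the lower direction. None of the 8 passed the threshold, although the groups did not overlap in any of them. The retinoic acid carrier CRABP2 averaged 38.7 ± 7.40 and 102 ± 22.7 FPKM (SD, n = 3), a log2 difference of 1.37 (SE 0.20, limma adjusted p = 0.247). The tetraspanin TSPAN6 averaged 3.65 ± 3.30 and 36.0 ± 19.0 FPKM, and the phosphatase regulatory subunit PPP1R18 averaged 1.42 ± 0.610 and 4.43 ± 0.388 (limma adjusted p = 0.447 for both). ZP2, a glycoprotein of the zona pellucida that surrounds the egg, averaged 4566 ± 179 FPKM in the libraries labelled control and 3135 ± 96.3 in those labelled knockdown. Its log2 difference was -0.54 (SE 0.09, limma adjusted p = 0.447). GTPBP10, a GTPase of mitochondrial ribosome assembly, averaged 22.3 ± 3.10 and 11.8 ± 0.502 FPKM, and the vasopressin receptor AVPR1B averaged 4.29 ± 0.962 and 1.57 ± 0.330 (limma adjusted p = 0.447 for both). The kinetochore component ZWILCH averaged 13.3 ± 1.17 and 7.20 ± 0.713 FPKM, and RSBN1L averaged 2.07 ± 0.398 and 0.573 ± 0.214 (limma adjusted p = 0.463 for both).

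Across the transcriptome, 0 of 9730 genes passed the adjusted threshold of 0.05 with limma. At an unadjusted p under 0.05 there were 635 genes, 376 higher and 259 lower in the libraries labelled knockdown, against 486 expected by chance. The balance turned to 323 higher and 328 lower after median-ratio scaling and to 307 and 358 after quantile normalization. The groups did not overlap for 581 genes in the higher and 491 in the lower direction, 11.0% of those tested, where chance gives 10%. An absolute log2 difference of at least 1 was reached by 106 genes, and the median SE was 0.18. The other splits of the 6 libraries into groups of 3 gave from 181 to 895 genes at an unadjusted p under 0.05, so 635 lay within their range. Without knockdown 2 the count was 336 and without control 3 it was 451, both under the 486 expected. It stayed above 486 when any other library was left out. The other limma settings that were run called between 0 and 2 genes. In data simulated for this comparison on 9730 genes, with 200 genes changed, the same test recovered 3.5% of log2 changes of 0.5. It recovered 61.1% of changes of 1, 97.1% of changes of 2 and 99.5% of changes of 3. The simulated genes varied independently, and the changed ones were drawn only from genes with a mean log2 level above 2. The shares also rest on the assumed 200 changed genes, because the Benjamini-Hochberg cutoff loosens as more genes change. They need not hold in the real libraries, where ISG15 and IFI6 did not pass at log2 differences of 3.89 and 3.63. The labels do not say whether the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which can be technical.

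**Figure D3:**
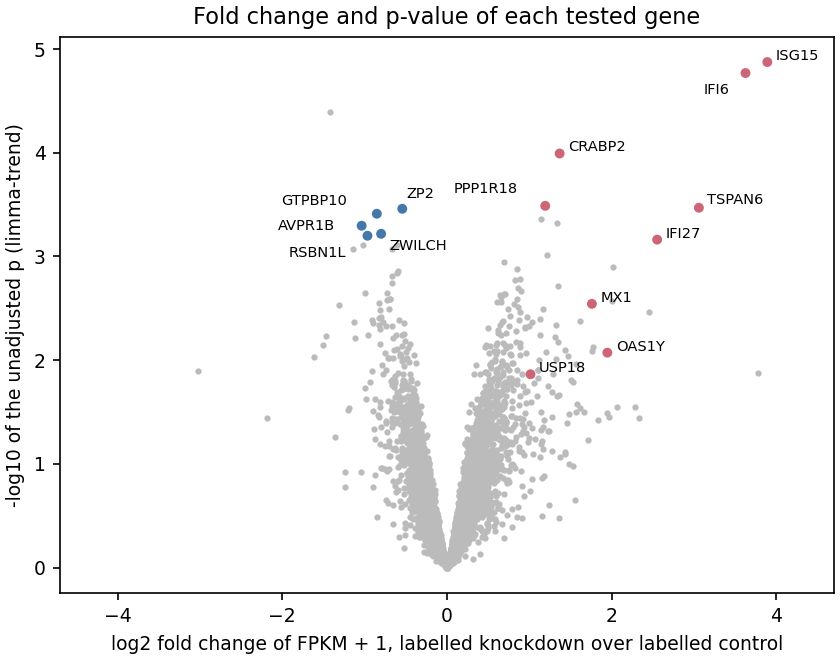
Log2 fold change of FPKM + 1 between the libraries labelled knockdown and those labelled control (horizontal axis) against -log10 of the unadjusted limma p (vertical axis) for each of the 9730 tested genes in grey, with named genes in red where higher and blue where lower. ISG15 and IFI6 lie farthest up at log2 fold changes of 3.89 and 3.63, and 0 genes pass the adjusted threshold of 0.05.

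Mitochondrial groups other than the target did not pass as lists, and 0 of their members passed either over all genes or adjusted over the list alone. Of the 25 tested genes for mitochondrial fission, fusion and cristae, 11 were higher and 14 lower, and 0 reached an unadjusted p under 0.05 (camera adjusted p = 0.831). The fission adaptor FIS1 averaged 4.86 ± 1.04 and 7.95 ± 4.10 FPKM (SD, n = 3), and the fusion GTPase MFN2 averaged 1.84 ± 0.191 and 1.32 ± 0.237. Mitochondrial ribosomal proteins had a higher mean in 52 of 79 genes (camera adjusted p = 0.208), of which 11 were higher and 1 lower at an unadjusted p under 0.05. The largest 2 log2 differences among their named members were those of MRPS2, which averaged 2.92 ± 0.200 and 6.35 ± 1.60 FPKM, and MRPL40, which averaged 4.60 ± 0.860 and 7.93 ± 0.990. Mitochondrial protein import had 19 of 26 genes higher (camera adjusted p = 0.208), among them the outer membrane protein MTX1 (log2 difference 0.68) and the intermembrane chaperone TIMM13 (0.33). Nuclear genes of respiratory complex I had 19 higher and 18 lower of 37 (camera adjusted p = 0.570), led by NDUFB7 at 23.8 ± 3.37 and 38.2 ± 6.77 FPKM. With the preset correlation these 3 lists passed without knockdown 1, while with all 6 libraries each had an adjusted p = 0.965 with an estimated correlation. With the preset correlation the camera adjusted p over the settings ranged from there upward: 1.71e-04 to 0.926 for complex I, 1.68e-04 to 0.975 for mitochondrial ribosomal proteins and 0.0292 to 0.851 for protein import. Without knockdown 3, complex I and mitochondrial ribosomal proteins turned to the lower direction, as did complexes II to IV without knockdown 2 or knockdown 3. Complexes II to IV had 16 of 26 genes higher (camera adjusted p = 0.889, with a range over the settings from 0.0397 without knockdown 1 to 0.983, and an adjusted p = 0.965 with an estimated correlation), with COX4I1 at a log2 difference of 0.58. The 18 ATP synthase genes went both ways (camera adjusted p = 0.870), with ATP5PB at 0.29 and ATP5ME at -0.32. Mitochondrial DNA maintenance (14 genes, GABPA at -0.51), permeability transition and nucleotide exchange (14 genes, the creatine kinase CKB at 0.89) each gave a camera adjusted p of 0.696. Mitophagy and autophagy (30 genes, LAMP1 at 0.51) gave 0.495.

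Single genes of redox defence and glycolysis were at higher mean levels in the libraries labelled knockdown, while neither group passed as a list and 0 of their members passed over all genes or adjusted over the list alone. In antioxidant defence, 16 of 28 genes were higher (camera adjusted p = 0.696), and the 4 with the smallest p-values were all higher in the libraries labelled knockdown. Glutaredoxin GLRX averaged 138 ± 9.53 and 322 ± 128 FPKM (SD, n = 3), a log2 difference of 1.13 (SE 0.29, limma adjusted p = 0.583). Without knockdown 1 its log2 difference was 1.51 (limma adjusted p = 0.0444, the lowest of a range over the settings up to 1.00). The glutathione peroxidase GPX1 averaged 21.1 ± 9.82 and 46.6 ± 11.5 FPKM, the mitochondrial thioredoxin TXN2 4.50 ± 1.71 and 7.97 ± 0.780, and the peroxiredoxin PRDX2 419 ± 62.0 and 555 ± 64.4. In glycolysis and the pentose phosphate pathway, 14 of 20 genes were higher (camera adjusted p = 0.208, with a range from 0.00854 without control 1 to 0.824, and an adjusted p = 0.965 with an estimated correlation). Pyruvate kinase PKM averaged 7.51 ± 3.21 and 21.3 ± 18.1 FPKM and the dehydrogenase GAPDH 65.4 ± 19.2 and 134 ± 77.5, while hexokinase HK2 averaged 3.46 ± 1.05 and 1.95 ± 0.460. The library labelled knockdown 2, in which the cumulus marker mean was highest, also had the highest enolase ENO1 (40.3 FPKM), PKM (42.2) and GAPDH (218). The tricarboxylic acid cycle (21 genes, IDH3B at 0.79 and DLD at -0.38) gave a camera adjusted p of 0.758, and fatty acid oxidation and lipid droplets (17 genes) gave 0.990.

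Stress and quality control lists did not pass either. Endoplasmic reticulum stress had 14 of 21 genes higher (camera adjusted p = 0.351), with the stress sensor ERN1 at a log2 difference of 0.65 and the chaperones CALR at 0.57 and HSP90B1 at 0.30. Cytosolic heat shock proteins had 11 of 14 higher (0.234), with the transcription factor HSF2 at 0.42. The mitochondrial unfolded protein and integrated stress response (22 genes, CHAC1 at 0.30 and DDIT3 at -0.18) and apoptosis (22 genes, CASP2 at 0.56) each gave 0.870. The proteasome had 23 of 31 genes higher (0.386, with a range from 0.0265 without control 1 to 0.824, and an adjusted p = 0.965 with an estimated correlation), with PSMC5 at 0.61 and PSMD14 at -0.36. In the p53 pathway and DNA damage response (24 genes, camera adjusted p = 0.499) the damage-marking histone H2AFX averaged 357 ± 64.0 FPKM in the libraries labelled control and 231 ± 33.4 in those labelled knockdown (SD, n = 3). In these lists 0 members passed over all genes and 0 adjusted over the list alone.

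Genes of the oocyte and of meiosis did not pass as groups. Of 34 oocyte-specific and maternal effect genes, 22 were higher (camera adjusted p = 0.744), and 1, ZP2, passed in the lower direction adjusted over the list alone, with 0 over all genes. UHRF1, which maintains DNA methylation, averaged 412 ± 135 and 741 ± 200 FPKM (SD, n = 3), and the groups overlapped. The meiotic cell cycle regulators (35 genes, the anaphase activator CDC20 at a log2 difference of 0.26) and the spindle, kinetochore and checkpoint genes (39 genes, the kinetochore protein NUF2 at -0.34) also gave 0.744. Camera adjusted p-values were 0.870 for meiotic cohesin and synapsis (19 genes, TEX12 at -0.43) and 0.930 for actin and polar body extrusion (28 genes, ACTG1 at 0.73). They were 0.928 for maternal mRNA translation and decay, where the translational regulator DAZL averaged 30.3 ± 14.7 and 54.9 ± 10.2 FPKM, and for the small RNA machinery (17 genes, TARBP2 at 0.51). Calcium handling and egg activation (22 genes) gave 0.889, and chromatin modifiers (23 genes, the deacetylase HDAC2 at 0.44) gave 0.631.

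Cytosolic ribosomal protein genes had a slightly lower mean in the libraries labelled knockdown in 53 of 81 members, with a median log2 difference of -0.09. The list had a camera adjusted p = 0.0337 with the preset correlation and 0.965 with an estimated correlation, and a fry adjusted p = 0.970. RPS29 averaged 1767 ± 230 and 1198.5 ± 272 FPKM (SD, n = 3), and RPL36A had a log2 difference of -0.82 (SE 0.33). In this list 0 members passed over all genes or adjusted over the list alone. The call ended without control 2 (camera adjusted p = 0.772, in a range from 5.26e-16 without knockdown 3) and turned to the higher direction without knockdown 1 (0.0847), and it also ended with no filter, with array weights and under median-ratio or quantile scaling. Replication-dependent histones, with 23 of 41 lower, gave a camera adjusted p of 0.0511, and several near-identical copies make each of their values uncertain. HIST1H1D averaged 8.29 ± 1.85 and 4.00 ± 1.27 FPKM, HIST2H2BE averaged 10.6 ± 3.21 and 5.14 ± 1.09, and HIST1H2AJ went the other way at 429 ± 86.0 and 649 ± 82.9. With the preset correlation the histone list passed without control 1 (4.51e-04), without control 2 (5.41e-04), without knockdown 3 (6.12e-04) and with FPKM rescaled to equal sums (0.0260), and its direction turned without control 3 (0.781). With all 6 libraries it had an adjusted p = 0.965 with an estimated correlation.

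Cumulus and granulosa markers did not pass as a list. Of 18 tested cumulus and granulosa markers, 11 were higher (camera adjusted p = 0.696). The protease inhibitor SERPINE2 averaged 14.5 ± 1.69 and 28.6 ± 13.0 FPKM (SD, n = 3), the filament protein VIM 2.77 ± 3.40 and 8.36 ± 4.80, and the inhibin subunit INHA 1.54 ± 0.771 and 7.87 ± 7.21. The matrix-binding TNFAIP6, made by expanding cumulus cells, averaged 7.99 ± 8.15 and 1.69 ± 1.00 FPKM. TIMP1, chosen like LUM and SPARC after its values were seen, was at 190.71, 13.14 and 156.93 FPKM in the libraries labelled control and 24.96, 955.49 and 32.02 in those labelled knockdown. Of the theca, stromal and fibroblast markers only 4 were tested, too few for the list test. LUM stood at 22.85 FPKM in knockdown 2 and at 0.38 to 7.39 in the other libraries, and SPARC had a log2 difference of 1.36 (SE 0.49). The 5 blood and endothelial markers gave a camera adjusted p of 0.870, with the haemoglobin gene HBA at 60.3 ± 14.6 and 35.7 ± 19.2 FPKM. None of these markers passed over all genes or adjusted over the list alone.

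**Figure D4:**
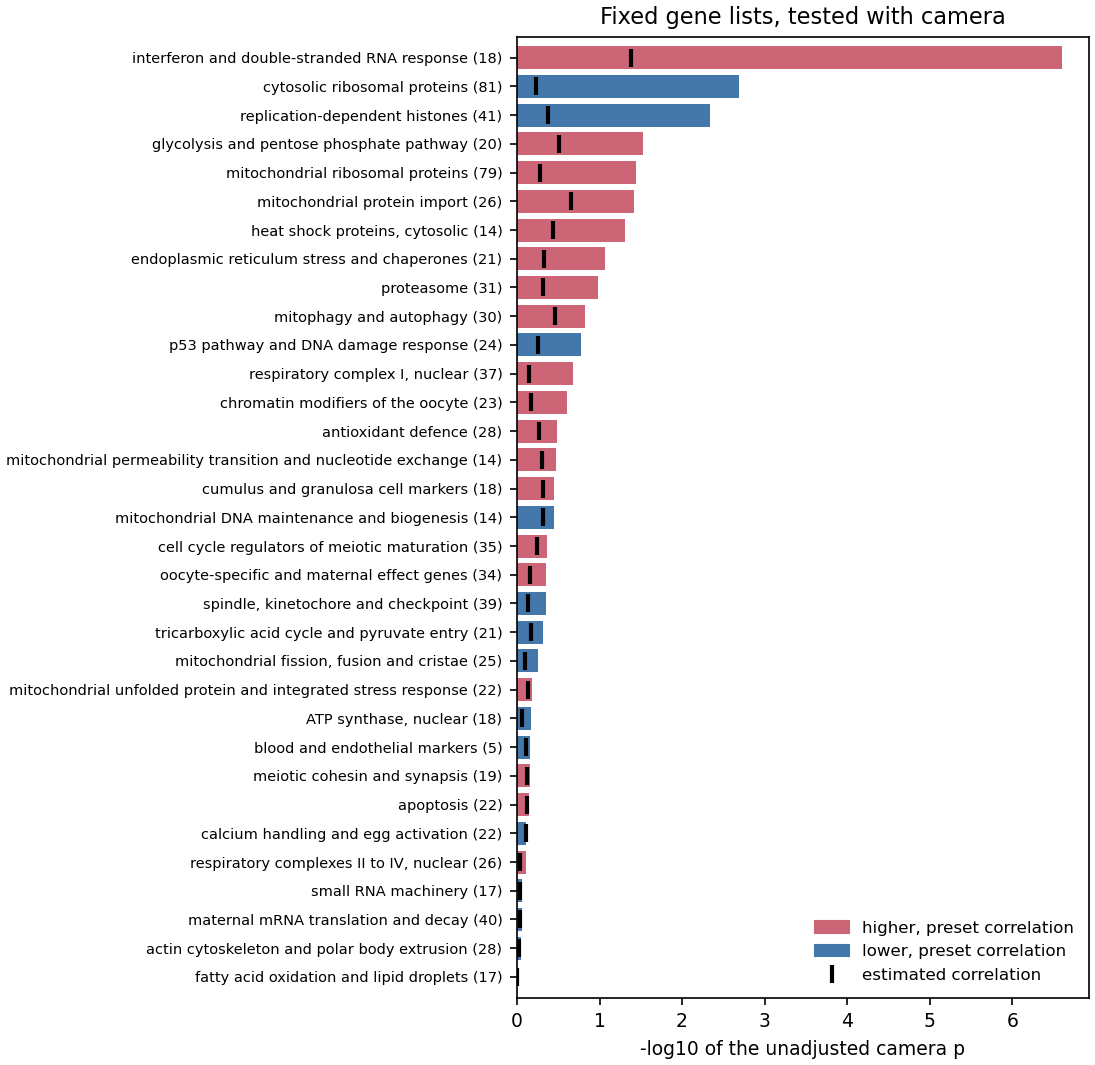
Unadjusted camera p of the 33 tested gene lists as -log10 (horizontal axis), with the number of tested genes in brackets, bars in red for lists higher and blue for lists lower in the libraries labelled knockdown at a preset correlation of 0.01, and black ticks for the p with an estimated correlation. The interferon list stands apart with the preset correlation (p = 2.53e-07), and its p with an estimated correlation was 0.0410.

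Of the 33 tested lists, 2 passed with the preset correlation, the interferon and the cytosolic ribosomal ones, 0 passed with an estimated correlation (smallest adjusted p = 0.965) and 0 by fry. Nearly all lists shared this adjusted p of 0.965, so it does not rank them. Before adjustment the camera p with an estimated correlation was 0.0410 for the interferon list and 0.584 for the cytosolic ribosomal list. In 11 of the lists, all with a camera adjusted p of 0.499 or more, the median, the mean and the direction of the test differed in sign.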

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

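Camera on ranks, the cumulus marker covariate and the interferon list without its 6 leading members were chosen only after the result was seen; the other settings were fixed before the data were examined. The count of genes past limma's adjusted threshold was 0 with 635 genes at an unadjusted p under 0.05, and 2 (ISG15 and IFI6) with a mean FPKM of at least 5 or with FPKM rescaled to equal sums, and 1 (ISG15) with the covariate. It ranged from 0 to 2 when 1 library was left out: GLRX without knockdown 1, IFI6 without knockdown 2, IFI6 and LOC112441545 without knockdown 3, and 0 without any control. The count at an unadjusted p under 0.05 fell from 635 to 336 of 9730 tested genes without knockdown 2 and to 451 without control 3. The same count was 1041 of 17318 tested genes with no filter and 1080 of 9730 with array weights. It split into 376 higher and 259 lower genes as deposited, 364 and 208 after rescaling to equal sums, 323 and 328 after median-ratio scaling, and 307 and 358 after quantile normalization, while the median log2 difference of all genes stayed within 0.03 of 0 under each scaling. MTFP1 was higher in the libraries labelled knockdown in all settings that gave a value, by 0.09 (pseudocount 5) to 0.96 (pseudocount 0.1), and by 0.14 to 0.44 when 1 library was left out. The interferon list passed in 16 of 16 fixed settings (camera adjusted p from 6.57e-07 to 0.0196, the latter with no filter; 3.63e-07 to 5.41e-04 when 1 library was left out), on ranks (0.0181) and with the covariate (4.01e-06), but not without its 6 leading members (0.499). Each of these used camera with a preset correlation, and the removed 6 were picked by their p-values, so a weaker result was bound to follow. The call was lost with an estimated correlation (camera p = 0.0410 before and 0.965 after adjustment) and by fry (adjusted p = 0.677). The number of lists called was 2, but 1 with no filter, median-ratio scaling, quantile normalization or array weights, and 3 with a mean FPKM of at least 5 (glycolysis added) or FPKM rescaled to equal sums (histones added). It was 2 to 5 when 1 library was left out, with 5 without control 1 and 5 without knockdown 1, and 3 without knockdown 3. The ribosomal list ranged from 5.26e-16 without knockdown 3 to 0.772 without control 2 and turned to the higher direction without knockdown 1 (0.0847); the cause was not tested. TIMP1 ranged from -1.36 without knockdown 2 to 1.24 without knockdown 1, and was -0.89 without control 2; LUM ranged from -0.54 without knockdown 2 to 1.53 without control 1. Other named genes kept their direction. Libraries with the same replicate number did not deviate together (correlations 0.03, -0.16 and 0.07), and control 1 was closest to knockdown 2 (0.23); the replicate block left 0 genes, 2 lists and the interferon list at 1.04e-04, and changed no call. Count tools, and array weights, robust fits and the fold minimum for MTFP1 and robust fits and the fold minimum for the lists, were not run. Unknown depth limits genes near 0 such as MTFP1.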

Other observations

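The use of the fixed setting without knockdown 2 as a test against a single library and the count of splits for genes as a test were chosen only after the result was seen, as were IFNB1, LOC112441545 and IFITM1 as examples; the covariate fit and the second interferon list were chosen after the interferon result but before their own values were seen.

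A second list of 40 interferon-stimulated genes had 16 tested members, 10 higher and 6 lower in the libraries labelled knockdown, with a median log2 difference of 0.15 (camera p = 0.0509, and p = 0.236 with an estimated correlation). The antiviral membrane protein gene IFITM1 was at 51.19, 2.99 and 6.32 FPKM in the libraries labelled control and 32.40, 122.84 and 41.95 in those labelled knockdown. By limma, 0 of the 16 passed over all genes or adjusted over the list alone, and 3 were higher at an unadjusted p under 0.05. The interferon gene IFNB1 was at 11.14, 3.02 and 0.71 FPKM against 3.82, 16.62 and 18.43, a log2 difference of 1.44 (SE 0.73, limma adjusted p = 0.801) with overlapping groups. LOC112441545 was at 16.21, 15.37 and 31.05 FPKM in the libraries labelled control, and was listed at 0 in knockdown 1 and 2 and at 15.96 in knockdown 3.

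MTFP1 was not lower in the libraries labelled knockdown. Whether its level is too near 0 for a loss to be measured stays open. Of the 500 genes nearest in mean FPKM, 1.2% had a knockdown to control ratio of 0.3 or less. That share does not tell whether a real loss would be masked. A loss of 70% would need a ratio of 6.37 from noise to end at the 1.91 seen, and 1.4% of these genes reached that. This second share assumes the size of the loss and rests on genes near 0. MTFP1 itself ran from 0.05 to 0.55 FPKM within the libraries labelled control. A swap of control 3 and knockdown 3, the libraries with the lowest and highest MTFP1, stays open: 321 genes passed an unadjusted p of 0.05 after the swap against 635 as labelled, but this count does not tell right labels from wrong ones, since 2 mixed splits reached 810 and 895, and 7 lists passed after the swap against 2, while the interferon list had a camera p of 0.103 after it against 2.53e-07. A knockdown that acted on the protein, a recovered transcript and a wrong label with no partner in the series stay open and untested.

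Of 18 tested interferon list members 14 had a higher mean and 4 a lower one in the libraries labelled knockdown. By limma 6 of them were at an unadjusted p under 0.05, all higher, and 0 passed the threshold over all genes. The list call held with a preset correlation but not by camera with an estimated correlation (p = 0.0410 before and 0.965 after adjustment). Residual cumulus cells stay open. With the cumulus marker mean as a covariate the median log2 difference of the 6 leading members was 1.98 against 2.25 before. The list had a camera adjusted p of 4.01e-06 with the preset correlation. Without its 6 leading members and without the covariate it had 0.499, which was bound to be weaker because the 6 were picked by their p-values. This fit cannot decide, because the marker mean did not separate the groups, so adjusting for it could change the group differences little. It did narrow the spread of ISG15, whose SE went from 0.44 to 0.21 with the covariate. Within the libraries labelled control, ISG15 followed the order of the mean (8.39, 2.12 and 4.36 FPKM in control 1, 2 and 3), while IFI27 and MX1 did not. Control 1 (3.67) and control 3 (3.44) had a higher mean than knockdown 1 (3.21) and knockdown 3 (3.30), but lower levels of each of the 6 members. Control 2 (2.75) had the lowest mean and knockdown 2 (3.80) the highest. The mean also joins markers that went both ways. SERPINE2 was higher in each library labelled knockdown than in each labelled control. VIM and INHA had higher means and TNFAIP6 a lower one. With the preset correlation a single library is argued against, since without knockdown 2 the list had a camera adjusted p of 3.63e-07 (3.63e-07 to 5.41e-04 over the libraries left out). The second list did not reach the threshold of 0.05 that was set for a wider response before its values were seen. Its camera p was 0.0509, and 0.236 with an estimated correlation. A wider response was therefore not shown, and with 10 of 16 members higher it is not excluded. A response to the knockdown treatment and cells of a type outside the lists stay open and untested. The titles of the libraries labelled knockdown begin with siMTFP1, which reads as a small interfering RNA against MTFP1. The treatment is confounded with the group, and the labels do not say what the negative control received. MTFP1 was also not lower, so no library separates a loss of MTFP1 from the introduced material.

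With 6 libraries there are 10 splits into groups of 3, too few for a share under 0.05. As many genes as the real split came from 10 of 10. This was fixed in advance, because the real split called 0 genes, so it decides nothing. The highest of the other splits called 1 gene. As many lists (2) came from 8 of 10, and the highest other was 12 lists, for control 1, knockdown 2 and knockdown 3 against the rest, all with the preset correlation. With the real groups the estimated correlation within lists ran from 0.0067 (calcium handling) to 0.595 (cytosolic ribosomal), against the preset 0.01. It was 0.389 for complex I, 0.328 for histones and 0.149 for the interferon list. Whether the number of lists called reflects a structure of the libraries or this correlation was not tested. An interferon list p as small as the real 2.53e-07 came from 1 of 10, the real split itself, and the smallest other was 0.00255.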
